A study of Mus musculus with 2 samples.

How the data were processed

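LSK cells were sorted from femur and tibia marrow of C57BL/6 mice at week 12 after sham or CLP surgery, after magnetic depletion of lineage-positive cells and staining for lineage markers, Kit and Sca1. Libraries were made with the Chromium 3′ v3 kit, 1 per group. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10. The labels give Cell Ranger version 2.1.1 and the matrix headers 4.0.0, and which was run could not be settled. The lowest barcode of each matrix holds 500 UMIs, so the matrices are filtered barcode sets. Both list 31053 genes, of which 30934 were found in the GENCODE M21 annotation that gave positions.

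Cells with at least 1000 detected genes and under 10% of UMIs from mitochondrial genes were kept, which removed 11.6% of sham and 6.51% of CLP barcodes. Scrublet, run on each library alone through scanpy 1.11.5 with an expected rate of 5%, called 2 doublets in each library and therefore hardly removed any. Counts were summed over kept cells (94597220 UMIs in the sham and 138703828 in the CLP library) and given as counts per 1000000 (CPM). Ratios are CLP over sham with exact conditional binomial intervals of 95%, which cover counting error only. A gene counted as differing in size at a ratio of at least 1.5 in either direction and at least 20 CPM in either library. No test was applied, since cells are not replicates and each group has 1 library. As far as counting error goes, the precision of single genes follows from their UMIs. In data simulated with counting error alone, the intervals held the true ratio for 94.0% to 97.0% of changed genes. All genes simulated at 2-fold and 4-fold were counted, and none at 1.2-fold. That coverage follows from how the data were simulated, and genes whose UMIs lie mostly in few cells were not simulated.

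For each of 37 gene lists the median log2 ratio over members with at least 10 CPM in either library was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. A list stands apart under percentile 2.5 or over 97.5, and lists with fewer than 3 members give values only.

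For cell classes, counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without mitochondrial, ribosomal, hemoglobin, sex-linked and cell cycle genes, gave 30 principal components, 15 nearest neighbours and Leiden clusters at resolution 1 (igraph 0.11.9), with no correction between libraries because library and surgery are the same split. Naming was set after seeing the data. A class was a candidate for a cluster if at least 3 markers and at least 50% of its list were raised 1.5-fold at 10 CPM or more, and at least 1 was among the 10 leading genes. The candidate with the most markers among the leading genes gave the name, if every other class had at most 1 there or fewer than its number divided by 2, and a tie at 1 went to the class with at least 2 times as many raised markers whose marker ranked first. Shares have exact Clopper-Pearson intervals of 95%. Sums within a class used genes with at least 100 CPM. For cell cycle shares and shares of cells with a gene, each cell was thinned to 5000 UMIs and shallower cells (195 sham, 203 CLP) were left out.

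The lists, the size rule and the rule for named genes were fixed before the data were examined. Named are the 12 genes highest and 12 lowest in ratio at 50 CPM or more, up to 4 members of each list with the largest ratio in either direction, every member of the TIMP1 list with any UMI, and the 5 highest and 5 lowest genes within each named class of at least 200 cells in both libraries. Left out of the first and last parts were unnamed gene models and mitochondrial, ribosomal, sex-linked, immunoglobulin and T cell receptor genes. Genes named outside the rule are marked as such.

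Alternatives covered scaling (edgeR 4.0.16 TMM, DESeq2 1.42.0 size factors, the mean of per-cell CPM), cell filters, doublets, thinning, CPM minimums, 2-fold size, pooled cluster weights, clustering settings and the thresholds of cell cycle counts. Pooled cluster weights average the CPM of the 16 clusters with at least 20 cells in both libraries by their share of all cells; clusters stand in for classes because most cells had no class name. Leaving out the 3 richest cells of each gene, the cluster led by Elane, the B cell clusters or the 5% of cells with the highest doublet score, and clustering without the genes 1.5-fold apart, were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3 were used.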

Results

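Single-cell RNA was counted in LSK cells, the lineage-negative, Sca1-positive, Kit-positive fraction of mouse bone marrow that holds hematopoietic stem cells (HSCs) and multipotent progenitors. C57BL/6 mice had sham surgery or cecal ligation and puncture (CLP), an operation that lets gut bacteria into the abdomen and causes sepsis, and marrow was taken at week 12 after surgery. Each group has 1 library. The labels speak of 3 mice without saying whether that is per group. With no replicates, no test between the groups was possible and no spread between animals is known. Values of the 2 libraries are therefore set side by side, and every interval covers counting error only.

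The sham library held 6331 barcodes with 95752787 unique molecular identifiers (UMIs, tags that mark single RNA molecules). Of these barcodes 5593 were kept as cells, with a median of 14676 UMIs and 2985 detected genes. The CLP library held 7848 barcodes with 140192169 UMIs, and its 7335 kept cells had a median of 16186 UMIs and 3279 genes. The mitochondrial share of UMIs in kept cells had a median of 5.40% in the sham and 4.97% in the CLP library.

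The study's title concerns lasting production of myeloid cells after severe infection, and the first comparison asks which transcripts of the LSK fraction differed between the libraries 12 weeks later. Transcripts of several neutrophil granule proteins were higher in the CLP library. Among them were Elane (neutrophil elastase) at 143 against 15.9 counts per 1000000 UMIs (CPM), Ctsg (cathepsin G) at 548 against 97.6 and Prtn3 (proteinase 3) at 868 against 239. Ifitm1, an interferon-inducible membrane protein, stood at 1167 against 346 CPM. Transcripts of antigen presentation were lower, with Cd74 (the MHC class II invariant chain) at 218 against 600 CPM and H2-Aa at 77.3 against 267. The granzyme Gzmc, at 24.3 against 88.5 CPM, and the chemokine Ccl3, at 105 against 253, were lower as well. Of 4892 genes with at least 20 CPM in either library, 421 were at least 1.5-fold higher and 184 at least 1.5-fold lower in the CLP library, while the median log2 ratio of all was 0.08.

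Among the 12 genes with the highest ratio, Ms4a3, which marks granulocyte-monocyte progenitors, had a ratio of 11.9 (interval 10.8 to 13.0), Elane 8.99 (8.53 to 9.48), Ctsg 5.62 (5.50 to 5.74), Prtn3 3.64 (3.58 to 3.69) and Ifitm1 3.37 (3.33 to 3.42). Lgals1 (galectin-1) had a ratio of 3.24, Ap3s1 3.17, Rab44 3.02 and Cst7 (cystatin F) 2.96. The remaining 3 rested on few cells. S100a8 and S100a9, the calprotectin subunits of neutrophils, had ratios of 293 and 204, but the 3 cells richest in each held 97.4% and 97.8% of its CLP UMIs, and the ratios without the 3 richest cells of each library were 11.1 and 6.07. Jchain, the joining chain of secreted antibodies, had a ratio of 6.66, but 97.45% of its sham UMIs lay in 3 cells, and the ratio was 0.823 among cells with at least 2000 genes and under 5% mitochondrial UMIs, 175 without the 3 richest cells of each library and 269 without the 5% highest doublet scores. In the sham library the 3 richest cells also held 61.4% of the Elane UMIs, and without the 3 richest cells of each library the Elane ratio was 21.8.

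Among the 12 genes with the lowest ratio, H2-Aa (0.290), H2-Eb1 (0.337) and Cd74 (0.364) belong to MHC class II presentation. Gzmc (0.274) and Gzmb (0.352) encode granzymes, Xcl1 (0.330) and Ccl3 (0.414) chemokines, and Bcl2a1d (0.283) and Bcl2a1b (0.291) survival factors of the BCL2 family. The others were Hilpda (0.314), a hypoxia-inducible lipid droplet protein, Cd83 (0.396) and Ankrd33b (0.396). None of these 12 had more than 6.31% of its UMIs in the 3 richest cells of either library.

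**Figure D1:**
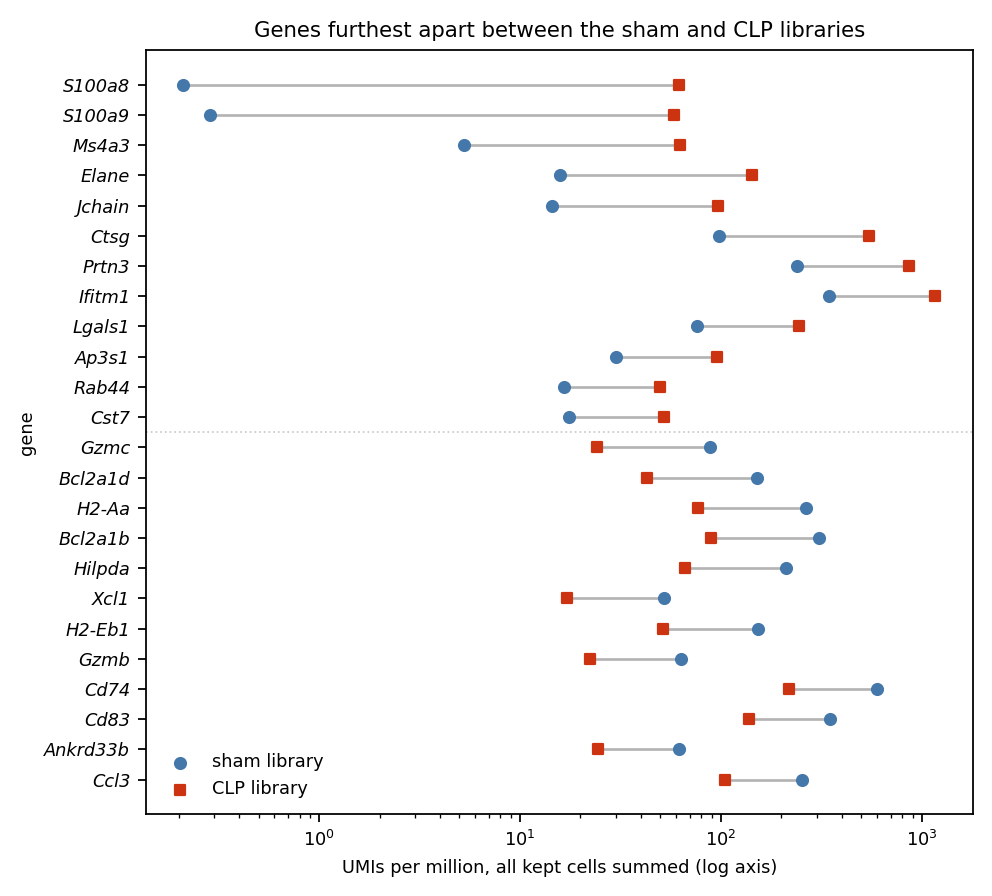
Counts per 1000000 UMIs (CPM) of the 12 genes with the highest and the 12 with the lowest CLP over sham ratio, among genes with at least 50 CPM in either library. Circles are the sham and squares the CLP library (1 library each, log axis). S100a8 runs from 0.211 to 61.9 and Gzmc from 88.5 down to 24.3.

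Elane and Prtn3 are neighbours on chromosome 10 of mm10, at 79886247 to 79888215 (ENSMUSG00000020125) and 79874476 to 79883174 (ENSMUSG00000057729). Ctsg lies on chromosome 14 at 56099881 to 56102574 (ENSMUSG00000040314) and Ifitm1 on chromosome 7 at 140967221 to 140969825 (ENSMUSG00000025491). H2-Aa, on chromosome 17 at 34282744 to 34287823 (ENSMUSG00000036594), is in the MHC region, and Cd74 is on chromosome 18 at 60803848 to 60812652 (ENSMUSG00000024610). All are annotated as protein-coding, and their counts are of 3′ ends.

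Some of these differences recurred inside clusters of like cells. Across the 13 clusters with at least 50 cells in both libraries, Ifitm1, Prtn3 and Lgals1 were higher in the CLP cells of all 13, and Bcl2a1d, Bcl2a1b, Hilpda and Cd74 lower in all 13, although over all B cell-like cells Cd74 had a ratio of 1.01 (interval 0.980 to 1.04). Igkc, an antibody light chain made by B lineage cells, was also higher in 12 of them. Yet 95.3% of its CLP UMIs lay in another cluster, with 16 CLP cells, so free RNA can give such recurrence too. The median ratio across those clusters was 3.33 for Ifitm1 and 0.533 for Hilpda. With each cluster given its pooled weight in both libraries, Elane turned to a ratio of 0.643. That value rests mainly on the cluster led by Elane, where 343 CLP cells stood at 1308 CPM of Elane and 20 sham cells at 2245. Outside that cluster Elane stood at 13.0 CPM in the CLP and 1.65 in the sham library. Under the same weights Ctsg (1.07), Rab44 (1.07), Ap3s1 (1.19), Prtn3 (1.43), H2-Eb1 (0.684), Cd74 (0.677) and Ankrd33b (0.775) were less than 1.5-fold apart. Ms4a3 (1.56), Bcl2a1d (0.550), H2-Aa (0.604) and Bcl2a1b (0.620) were then less far apart than over all cells but still at least 1.5-fold. The counts of genes at 1.5-fold under these weights were 32 higher and 47 lower. Without the cluster led by Elane, 240 genes were higher and 138 lower, and the ratio was 5.14 for Ms4a3, 5.69 for S100a8 and 3.74 for S100a9. Among cells with at least 2000 genes and under 5% mitochondrial UMIs it was 4.74 for Elane and 7.17 for Ms4a3.

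The gene lists, fixed before the data were examined, put these genes in context. Of 37 lists, 32 had enough members for a median, and 16 stood outside the central 95% of random lists of like expression, 6 higher and 10 lower in the CLP library. Among 600 random lists of 15 genes drawn from the same data, 7% stood outside that range. Those genes are unrelated, so this is no error rate for lists of related genes. The myeloid-primed markers had a median log2 ratio of 1.71, with 7 of 10 members at least 1.5-fold higher and none lower. Besides Elane, Ctsg, Ms4a3, Prtn3 and Cst7 these were Igsf6 (ratio 13.6) and Mpo (myeloperoxidase), at 633 against 224 CPM. Mpo was added after its values were seen. The transcription factors that drive myeloid fate did not stand outside the range (median -0.15, percentile 2.99): Cebpd had a ratio of 1.72, Klf4 0.605, Id2 0.617 and Myc 0.650. In 5 of 11 alternatives they did stand outside it, lower in the CLP library, with medians from -0.33 to -0.11.

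Proliferation and respiration lists were higher in the CLP library. S phase genes had a median log2 ratio of 0.54, with 13 of 37 members at least 1.5-fold higher, among them Rrm2 (ribonucleotide reductase, ratio 2.47) and Mcm2 (replication helicase, 1.75). G2M phase genes had a median of 0.45, with 11 of 39 higher and 1 lower, including Top2a (topoisomerase, 1.80) and Cdc20 (2.00). Nuclear genes of oxidative phosphorylation had a median of 0.46, with 17 of 75 higher and none lower, while mitochondrially encoded genes had -0.11 (percentile 5.50). The unfolded protein response list stood just outside the range at 0.29 (percentile 98.1), with members on both sides such as Sdf2l1 (2.45) and Herpud1 (0.605), and it was inside the range in 6 alternatives, for example 0.15 with cells thinned to equal depth. The mature neutrophil list had a median of 7.98 over 5 members, yet 2 CLP cells held 92.4% of its UMIs in that library.

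Lists of stem cell identity, quiescence and lymphoid priming were lower. All 6 measured HSC markers had ratios below 1 (median log2 ratio -0.55), for example Hlf at 0.654 and Cdkn1c, a cell cycle inhibitor, at 0.581. All 12 quiescence genes did too (-0.56), with 6 at least 1.5-fold lower, including Tob1 (0.480) and Foxo3 (0.588). The quiescence list shares Egr1, Btg2 and Nr4a1 with the immediate early genes and Cdkn1c with the HSC markers, so it is not independent of those lists. Lymphoid-primed markers had a median of -0.58, with Flt3 (a cytokine receptor of early lymphoid-competent progenitors) at 0.649 and Satb1 at 0.670, and lymphoid transcription factors had -0.36, with Notch1 at 0.636. Erythroid-primed markers had -0.72 over 3 members, led by Car1 (0.343), and -0.21 (percentile 6.14) with members of at least 1 CPM included.

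Lists of antigen presentation and of early response to stimuli were lower too. MHC class II genes had a median of -1.03 and MHC class I genes of -0.48, with 5 of 8 and 4 of 11 members at least 1.5-fold lower and none higher. H2-Ab1 had a ratio of 0.437, and the class I genes H2-Q6 and H2-Q7 had 0.429 and 0.520. Immediate early genes, induced within minutes by many stimuli, had -0.53, with 6 of 16 lower, among them Nr4a1 (0.522), Atf3 (0.531) and Fos (0.592). Targets of NF-kB and TNF had -0.26, with Nfkb1 at 0.690 but Il1b, an inflammatory cytokine, at 2.36. The type I interferon list had -0.21 (percentile 1.93), with Isg15 at 0.599 and Bst2 at 1.25, and was inside the range in 6 alternatives.

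With pooled cluster weights, 7 of the 16 lists no longer stood outside the range: HSC markers at -0.07, myeloid-primed markers at 0.10, lymphoid-primed markers at 0.03, lymphoid transcription factors at -0.05, NF-kB targets at 0.09, type I interferon at 0.09 and the unfolded protein response at -0.02. MHC class II (-0.38), MHC class I (-0.37), immediate early genes (-0.25), quiescence (-0.25), oxidative phosphorylation (0.22), S phase (0.13), G2M phase (0.16) and erythroid-primed markers (-0.49) still did, and mature neutrophil markers have no value under these weights. Clusters often hold cells mostly of 1 library, so such weights also remove differences that define clusters.

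**Figure D2:**
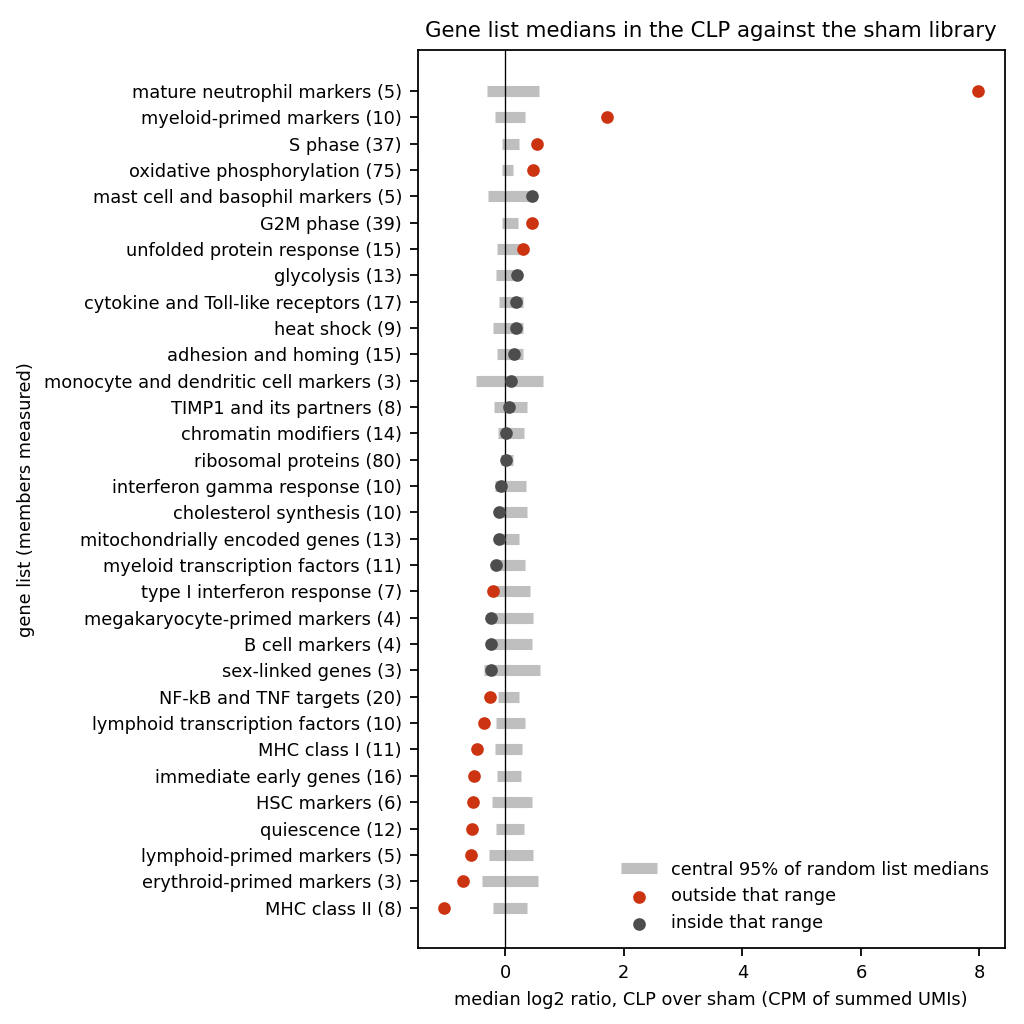
Median log2 CLP over sham ratio of each gene list (points) with the central 95% of medians of random lists of the same size and like expression (grey bars). Numbers in brackets are the members measured. Mature neutrophil (7.98) and myeloid-primed markers (1.71) lie furthest to the right and MHC class II (-1.03) furthest to the left.

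As reported, the other lists stayed inside the random range. Medians were -0.24 for megakaryocyte-primed markers, 0.10 for monocyte and dendritic cell markers, 0.46 for mast cell and basophil markers, -0.24 for B cell markers, -0.07 for the interferon gamma response, 0.18 for heat shock and 0.18 for cytokine and Toll-like receptors. They were -0.11 for cholesterol synthesis, 0.20 for glycolysis, 0.01 for ribosomal proteins, 0.02 for chromatin modifiers, 0.15 for adhesion and homing and -0.25 for sex-linked genes. Several stood outside it under alternatives. Mast cell and basophil markers did so in 5, on both sides, for example at 0.79 with cells thinned to equal depth and -0.37 with pooled cluster weights. Pooled weights also put megakaryocyte-primed markers (-0.16), the interferon gamma response (-0.10), cholesterol synthesis (-0.14) and adhesion and homing (0.22) outside. With members of at least 1 CPM, monocyte and dendritic cell markers (1.44), B cell markers (-0.40) and the interferon gamma response (-0.28) were outside, and with members of at least 50 CPM the interferon gamma response (0.53) and ribosomal proteins. B cell markers (-0.25 with the mean of per-cell CPM) and cholesterol synthesis (-0.18 when thinned) were too. Single members still differed, such as Csf2rb, a subunit of the GM-CSF and IL-3 receptors (ratio 2.35), Tlr2, a sensor of bacterial lipoproteins (2.52), Cd48 (2.33) and the homing receptor Cxcr4 (0.482). Some lists of cells that the sort should remove had few members to measure: none of the T and NK cell markers reached 10 CPM, and 1 each of the ILC2 (Rora, 0.612), erythroblast (Hbb-bt, 1.08), endothelial (Emcn, 0.585) and stromal (Pdgfrb, 1.99) markers did. Other such lists had more, with 4 B cell and 5 mature neutrophil markers at 10 CPM.

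TIMP1 is the niche factor named by the study, an inhibitor of matrix metalloproteinases that also binds CD63. Timp1 itself (X chromosome, 20870166 to 20874735, ENSMUSG00000001131) was nearly absent from both LSK libraries, with 9 UMIs in the sham and 21 in the CLP library, a ratio of 1.59 (interval 0.699 to 3.95), so that no difference was detectable at this depth. The ratio was 0.971 without a filter on cells and 0.860 among cells with at least 2000 genes and under 5% mitochondrial UMIs. The list of TIMP1 and its partners had a median log2 ratio of 0.06 over 8 members (percentile 47.4). Its receptor Cd63 stood at 282 against 275 CPM (ratio 1.02), and Itgb1 stood at 84.7 against 70.8. Among the proteases, Mmp14 was higher (5.83 against 1.60 CPM, ratio 3.65) and Adam17 too (1.52), while Adam10 had a ratio of 1.16 and Mmp2 of 0.668. Mmp8 had 47 UMIs in the CLP and 6 in the sham library and Mmp9 had 1 and 3. Of the other members, Lrp1 had a ratio of 0.615, Cd44 1.07, Timp2 0.825 and Timp3 0.726, and Timp4 had 1 UMI in the sham library alone.

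The next comparison concerns which kinds of cells made up the LSK fraction. HSC-like cells were 6.58% (interval 6.03 to 7.18%) of the CLP library and 9.85% (9.08 to 10.7%) of the sham library. Myeloid-primed-like cells, named for Elane, Ms4a3 and Ctsg, were 4.68% (4.20 to 5.18%) of the CLP library, 343 cells, and 0.358% (0.219 to 0.552%) of the sham library, 20 cells. Megakaryocyte-primed-like cells, led by Pf4 and Itga2b, were 6.64% (6.08 to 7.23%) and 3.49% (3.02 to 4.0%), and B cell-like cells 2.99% (2.61 to 3.40%) and 3.67% (3.19 to 4.19%).

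Because genes that differ between the libraries could define a cluster, cells were also clustered without the genes at least 1.5-fold apart, a choice made after seeing the data, although names still came from the markers. The shares in the CLP and sham libraries were then 8.59% and 14.97% for HSC-like, 8.25% and 0.483% for myeloid-primed-like, 6.33% and 3.38% for megakaryocyte-primed-like and 2.94% and 3.61% for B cell-like cells. Across 11 alternatives the HSC-like share was lower in the CLP library each time (ratio of shares 0.462 to 0.777), and the megakaryocyte-primed-like share higher each time (1.10 to 2.31). The myeloid-primed-like share was higher in the 10 that formed such a class (8.96 to 21.3), but its size in the CLP library ran from 4.19% to 21.4% with the resolution of the clustering. The B cell-like ratio, 0.815, was 1.44 in cells thinned to 5000 UMIs, where the class took in the cluster led by Igkc and Jchain (16 CLP cells and 1 sham cell), and 0.908 there without that cluster. The thinned class held only 40 CLP and 21 sham cells, against 219 and 205 before thinning, and the 0.908 rests on 24 and 20.

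The clusters left without a name held 79.1% of CLP and 82.6% of sham cells. A naming threshold set after seeing the data kept out 2 clusters with a myeloid-primed marker among their leading genes, which held 18.6% of the CLP and 1.47% of the sham library. It also kept out 2 with an HSC marker (22.2% and 21.6%) and 2 with a lymphoid-primed marker (8.96% and 31.3%). That marker was Dntt in both, named here after its values were seen. In 1 of them Dntt came last among leading genes that were otherwise mostly histone and cell division genes. Among thinned cells, 12.4% of CLP and 13.5% of sham cells had at least 1 UMI of Dntt. At least 3 UMIs were found in 3.93% and 3.56%. The shares of these 2 clusters therefore need not be shares of lymphoid-primed cells. In the 5 alternatives that formed a lymphoid-primed-like class, its share was lower in the CLP library in 3 (ratio of shares 0.381 to 0.760) and higher in 2, at 4.81% against 3.56% without the genes 1.5-fold apart and 4.08% against 3.58% without the highest doublet scores. Also without a name were a cluster with erythroid, mast cell and basophil markers (0.586% and 0.983%), a cluster led by T cell receptor genes (0.423% and 0.322%) and a cluster led by antibody genes (0.218% and 0.0179%). Of all 18 clusters, 7 drew over 80% of their cells from 1 library. Such a cluster can be a property of that library as well as a kind of cell.

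**Figure D3:**
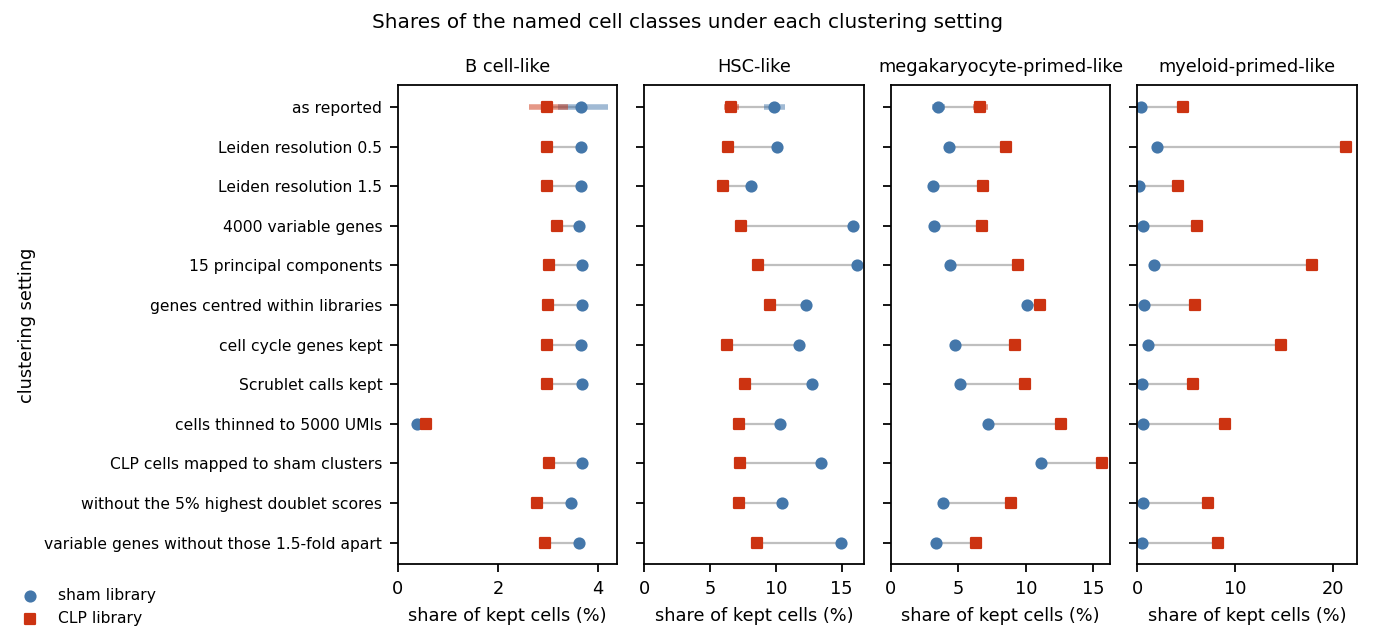
Share of kept cells in each named class in the sham (circles) and CLP (squares) library under the reported clustering and its alternatives. Thick bars in the top line are exact 95% counting intervals. HSC-like cells are 9.85% against 6.58% and myeloid-primed-like cells 0.358% against 4.68% as reported.

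Cells of 1 class were then compared between the libraries. Within HSC-like cells Lmna (lamin A/C) had a ratio of 2.25 (interval 2.06 to 2.46), Fut8 2.14, S100a6 2.09, Crip1 1.92 and S100a10 1.89. Cd83 had 0.326 (0.281 to 0.377), Hilpda 0.440, Hist1h2bc 0.475, Nr4a3, an immediate early nuclear receptor, 0.492 and Jdp2 0.497. Of 1210 genes with at least 100 CPM, 16 were at least 1.5-fold higher and 26 lower, and 9 and 41 with TMM scaling. The lists outside the random range in HSC-like cells were S phase (median log2 ratio 0.40), oxidative phosphorylation (0.19), quiescence (-0.37), immediate early genes (-0.42), MHC class II (-0.53), MHC class I (-0.41), the interferon gamma response (-0.30), megakaryocyte-primed markers (-0.27), myeloid transcription factors (-0.19) and myeloid-primed markers (1.04 over 4 members). The source of the last is open. In HSC-like cells Ctsg stood at 13.1 CPM in the CLP and 1.85 in the sham library and Mpo at 18.0 and 6.69, all below the B cell-like cells, which should lack both (Ctsg 27.9 and 23.6, Mpo 61.9 and 63.4). Prtn3 stood at 345.5 and 219.1 CPM, above the B cell-like cells (105.8 and 56.7). The B cell-like levels of Ctsg and Mpo hardly differed between the libraries, so they may not measure the background of HSC-like cells. B cell-like cells also held fewer UMIs (medians of 3359 and 3810 in their clusters, against 11309.5 in HSC-like cells). Like amounts of free RNA per cell would therefore give them a higher CPM. Mpo was also uneven within the B cell-like class. With libraries pooled it stood at 106 CPM in 1 of its clusters and at 8.32 in another, below the 18.0 of CLP HSC-like cells. Igkc, an antibody light chain made by B lineage cells, stood at 15.9 CPM in CLP and 2.85 in sham HSC-like cells. HSC markers, by which the HSC-like class was named, had 0.09 in its cells (percentile 50.04).

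Within B cell-like cells, 18 of 1385 genes were at least 1.5-fold higher and 11 lower. Ifitm1 had a ratio of 3.50 (2.83 to 4.38), Prtn3 1.87, Hist1h1b 1.78, Top2a 1.77 and Pou2f2 1.76, and Fosb had 0.482 (0.379 to 0.610), Tsc22d1 0.548, Myl4 0.572, Hist1h2bc 0.602 and Il21r 0.631. Prtn3 is not a B cell gene, and its level in these cells can include free RNA. The lists outside the random range in B cell-like cells were G2M phase (median log2 ratio 0.28), adhesion and homing (0.23), heat shock (0.21), S phase (0.17), glycolysis (0.17), oxidative phosphorylation (0.17), lymphoid transcription factors (-0.12), quiescence (-0.21), myeloid transcription factors (-0.32), immediate early genes (-0.35) and cholesterol synthesis (-0.52). MHC class II genes had -0.02 (percentile 41.0). Whether the classes differ from each other was not tested.

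The last comparison concerns cell division. After each cell was thinned to 5000 UMIs, 61.2% (interval 60.0 to 62.3%) of CLP cells and 44.2% (42.9 to 45.5%) of sham cells had at least 5 UMIs of S phase genes. For G2M phase genes the shares were 82.0% (81.1 to 82.9%) and 78.6% (77.5 to 79.7%). In HSC-like cells the G2M share was 72.8% (68.6 to 76.7%) in the CLP and 75.7% (71.9 to 79.2%) in the sham library, with overlapping intervals. Without thinning the G2M shares were 97.8% in both libraries. With at least 10 UMIs the S phase shares were 30.7% and 17.6%. For G2M phase genes they were 43.1% and 35.0%. The threshold of 5 UMIs is low for G2M phase genes, as the median thinned cell held 8 in the CLP and 7 in the sham library. The G2M shares at 5 UMIs may therefore hardly separate dividing from resting cells. UMIs of either list can also include free RNA from dividing cells, so they do not by themselves show cycling.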

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

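The tests of the Elane-led cells alone, of free RNA, of the mix of clusters as the whole cause and of a preparation effect on MHC class II genes were chosen only after the results were seen. The other tests of these patterns were set before their results were seen.

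Barcodes with fewer than 1000 genes and under 10% mitochondrial UMIs, which enter no comparison, held a transcript nearly absent from kept cells. Scgb1a1, a secretoglobin best known from airways and chosen after its values were seen, stood at 59806 CPM in such barcodes of the sham library and at 72288 CPM in those of the CLP library, against 0.338 and 0.433 CPM in kept cells. Its 57 richest sham and 48 richest CLP barcodes, each with at least 50 UMIs of the gene, included no kept cell, and all 48 had the sequence of 1 of the 57. Whether these transcripts belong to the library they were counted in is therefore open.

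The myeloid-primed markers, among them granule genes, were higher as a list in the CLP library. The cells of the Elane-led cluster do not account for this alone, since the median log2 ratio of the myeloid-primed markers without them was 1.31 (interval 1.23 to 1.33). Free RNA from those cells would keep their ratio of Elane to Mpo UMIs, but in the CLP library that ratio was 0.0335 outside the cluster and 0.462 inside, a quotient of 0.0725. This argues against free RNA from the Elane-led cells as the main source of Mpo outside them. It cannot decide for Elane, because other clusters also hold Mpo, for example at 1049 CPM with libraries pooled. Nor does it cover free RNA from other cells. With cells thinned to 5000 UMIs the median was 1.49 (1.34 to 1.56). CPM already divides by the UMIs of each library, so thinning was no test of depth as such. It gives each cell the same weight, so a greater weight of UMI-rich cells alone does not account for the difference. Open remain a different mix of clusters, since the median was 0.10 with pooled cluster weights, a persistent effect of sepsis on progenitors, a difference in the Sca1 gate between the sorts and a difference between the 2 preparations, which this design cannot separate.

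Immediate early genes were lower in the CLP library. A different mix of clusters is not the whole cause, because within HSC-like cells the median log2 ratio was -0.42 (-0.45 to -0.34). With pooled cluster weights it was -0.25, which leaves a part of the mix open. The interval for that value (-0.27 to -0.22) carries over the width for unweighted counts and may be too narrow. Immediate early genes respond to cell isolation, and in B cell-like cells, which went through the same preparation, the median was also low at -0.35 (-0.46 to -0.25). Handling and a biological effect of CLP cannot be told apart, since each surgery has 1 preparation.

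MHC class II genes were lower in the CLP library. A different number of B cells does not account for it, as the median was -1.09 (-1.13 to -1.04) without the B cell clusters, and neither does the mix of clusters as a whole, given -0.53 (-0.67 to -0.40) within HSC-like cells. The mix may hold a part, since the median was -0.38 with pooled cluster weights. Its interval (-0.43 to -0.34) carries over the width for unweighted counts and may be too narrow. In B cell-like cells, from the same preparations, the median was -0.022 (-0.13 to 0.05). That class pools a cluster with class II genes among its leading genes (133 CLP and 114 sham cells) and a cluster without them (86 and 91). Such a mix can hide a decrease. Cd74 was lower in all 13 clusters with at least 50 cells in both libraries, but with ratios up to 0.976. H2-Ab1 was lower in all 13 too (up to 0.893), while H2-Aa and H2-Eb1 were each higher in 1 (1.22 and 1.04). The B cell-like value therefore does not decide on a preparation effect. A lasting effect of sepsis on progenitors and a preparation effect, also one that spares B cell-like cells, remain open.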

How the results depend on the processing

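No paired analysis was possible because each group has 1 library and the labels link no mice between them. Of 1762 gene values under alternatives 1184 stayed within the counting interval, 570 moved and 8 of genes at least 1.5-fold apart reversed. Of 335 list values 291 kept sign and call, 19 became calls, 14 lost theirs and 11 changed sign. Of 111 main values 85 stayed, and of 40 within-class gene values 35. TMM and size factors changed the median log2 ratio of all genes by under 0.1. Alternatives that leave out the richest cells, the Elane-led or B cell clusters or the highest doublet scores, and clustering without genes 1.5-fold apart, were chosen after seeing the data.

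Genes at 1.5-fold, 421 higher and 184 lower, numbered 32 and 47 with pooled cluster weights, and 240 were higher without the Elane-led cluster. At a minimum of 50 CPM there were 195 and 104, at 5 CPM 801 and 381, and at 2-fold 58 and 51, by construction of fewer or more genes. Pooled cluster weights reversed Elane (0.643), Ly6c2 (0.874), Ung (0.973) and the list medians of lymphoid-primed markers (0.030), type I interferon (0.086), NF-kB targets (0.087), the unfolded protein response (-0.021), mast cell and basophil markers (-0.37) and B cell markers (0.072, and 0.21 when thinned). With members of at least 50 CPM interferon gamma (0.53), cytokine and Toll-like receptors (-0.29) and chromatin modifiers (-0.074) changed sign, and with at least 1 CPM cholesterol synthesis (0.0021). Jchain (0.823) and Timp1 (0.860) reversed with at least 2000 genes and under 5% mitochondrial UMIs, Timp1 also with no filter (0.971), and Ebf1 when thinned (1.01) or without B cell clusters (1.12, by construction of leaving out its cells). The Elane value rests mainly on the Elane-led cluster with its 20 sham cells. For the other reversals the cause was not tested.

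The B cell-like ratio of shares, 0.815, was 1.44 when thinned, where the class took in the cluster led by Igkc and Jchain, and 0.908 without that cluster, a value added after seeing the data. The 0.908 rests on 24 CLP and 20 sham cells. The HSC-like ratio, 0.668, was 0.462 with 4000 variable genes, 0.535 with 15 components, 0.777 with genes centred within libraries, 0.534 with cell cycle genes kept, 0.541 with CLP cells mapped to sham clusters and 0.574 without genes 1.5-fold apart. The megakaryocyte-primed-like ratio, 1.90, was 1.10 centred, 1.40 mapped and 2.31 without the highest doublet scores. Lists left with fewer than 3 members have no value, such as mature neutrophil markers in 4 of 11 alternatives. The myeloid-primed-like ratio, 13.1, has no value when mapped, as the sham clusters held no such class. Within HSC-like cells TMM gave 9 genes higher and 41 lower. The G2M ratio of shares, 1.04, was 1.00 without thinning and 1.23 at 10 UMIs, and the S phase ratio, 1.38, was 1.05, 1.74 and at 3 UMIs 1.17. The cause was not tested, except that without thinning 97.8% of cells in both libraries pass the G2M threshold. Depth limits Timp1 and other genes with few UMIs, and within B cell-like cells all genes near 100 CPM.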

Other observations

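No test was run on the following values, and their genes were chosen after the values were seen unless the rule for named genes took them.

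Cells rich in antibody transcripts were mostly of the CLP library. A cluster led by Igkc and Jchain held 16 CLP cells and 1 sham cell, and held 98.5% of the Jchain and 95.3% of the Igkc UMIs of the CLP library. Igkc was also higher in the CLP cells of 12 of the 13 clusters with at least 50 cells in both libraries, with a median ratio of 5.32. Most mature neutrophil transcripts came from 2 cells, as the neutrophil list made up 41.5% and 58.6% of all UMIs of the 2 richest CLP cells. The sort stained for B220, CD19, Gr1 and CD11b.

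Single genes of activation and identity differed across clusters. Il21r was lower in the CLP cells of all 13 clusters and Nr4a3 in all 12 where it was measured, and Fut8, S100a6 and S100a10 were higher in all 13. Ly6a, which encodes Sca1, was higher in all 13, with a median ratio of 1.94, but over all cells it stood at 38.9 against 33.0 CPM, and its ratio was 1.33 in HSC-like and 1.25 (interval 0.868 to 1.81) in B cell-like cells. Mmp14, a membrane-bound metalloproteinase, was higher in all 3 clusters where it was measured, with ratios of 2.77 to 7.74.

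Elane was seen in 6.77% of CLP cells and 0.574% of sham cells thinned to 5000 UMIs, and in none of 59 CLP and 48 sham B cell-like cells, which should lack it and for which a count of 0 allows up to 6.06% and 7.40%. Over all B cell-like cells, thinned or not, Elane had 6 UMIs in the CLP library (3.99 CPM, against 13.0 outside the Elane-led cluster) and none in the sham library, so some background is present. Pf4, a megakaryocyte gene, was seen in 9.48% of CLP and 14.7% of sham cells, the opposite order to the megakaryocyte-primed-like share, and in 3.39% and 10.4% of B cell-like cells, with intervals that reach 11.7% and 22.7%, so background is not excluded. In the Elane-led cluster Ly6a stood at 14.3 CPM in the CLP library, against 41.6 in all other cells and 104 in HSC-like cells, and Fcgr3, which encodes a receptor used to sort committed myeloid progenitors, at 28.2 against 2.90.

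Barcode sequences were shared between the libraries more often among barcodes with fewer than 1000 genes and under 10% mitochondrial UMIs. Of 501 such barcodes of the sham library, 376 (75.0%) carried the sequence of a kept CLP cell, with a median of 617.5 UMIs here and 44131 there. Of 214 in the CLP library, 57 (26.6%) carried that of a kept sham cell. Only 13 sequences were kept in both libraries. All 48 CLP barcodes rich in Scgb1a1 were among the 57 of the sham library. Elane stood at 604 CPM in such sham barcodes and at 60.4 CPM in the CLP ones. Reads assigned to the wrong library would give such sharing, which the count tables alone do not settle, so these values need not describe the library they were counted in.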
